A study of Mus musculus with 4 samples.

How the data were processed

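Pooled WT and pooled NaS1-/- mouse ileum RNA was compared on 4 arrays of 2 channels each. Per the labels' protocols, total RNA was extracted on columns and amplified and labelled by in vitro transcription. Per the file headers, the deposited intensity values are spot and local background medians from ImaGene 5, joined by BASE 1.2.10, with no background subtraction. The submitters' processing notes name limma, with no role or version. The deposited table of processed values holds signed values centred near 0, handled here as if they were log2 ratios. Their log base, numerator and whether any array was turned are not given in the sources used here, so scale and direction stay unknown.

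Each array had 25088 spots in 32 blocks, of which 21766 were probes, 2993 blank and 329 control spots. Intensities were read in R 4.3.3 and analysed with limma 3.58.1. Background was corrected with normexp at an offset of 50, and log2 Cy5/Cy3 ratios were normalized by loess within each array, with no scaling between arrays. Blank and control spots had weight 0. Spots flagged as empty or of poor quality were left out, which were between 312 and 433 empty and between 502 and 549 poor probes per array. Saturated spots, with a foreground median above 65000, were kept, between 39 and 67 per array in Cy3 and between 112 and 161 in Cy5. A probe passed the detection filter if its foreground median exceeded the background median by 2 background SD in at least 1 channel. This had to hold on at least 3 of the 4 arrays, which 21253 probes met. A fit also needed unflagged ratios on at least 2 arrays, or at least 3 with a dye term. This left 21055 probes in the labelled fit and 20849 in the pairings with a dye term. Some tests therefore rest on fewer than 4 arrays. Ratios were tested with lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05.

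The rule for each array's sign was fixed before the data were examined, as were the test, the filter, the gene lists and the rule for named genes. It asked in turn for channel contents in the headers, for 2 columns of the processed table running against their arrays, and for 2 arrays with r under -0.3 to the others. The headers name only the green and red channels. The rows of the processed table carry running numbers and were not matched to probes: in 2 orders with shifts of up to 60 rows, no column reached an absolute r above 0.065, and further orders tried while the files were examined gave no match either. No pair of arrays had an r below 0.714. The labelled dyes on all 4 arrays were therefore the main setting, as the rule prescribed. The 3 pairings, each with and without a dye term, and the 4 patterns with 1 array turned were added after the data were examined. The rule for named genes asked for the probes with the largest ratios that carry a gene symbol, which selected none here. The 4 identifiers printed were chosen after their values were seen.

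The fits were tested on simulated ratios of 19680 probes. Their noise had the residual spread that the turned fit with a dye term leaves on the measured ratios. For the labelled dyes with no dye effect, 97.0% of 66 probes changed by 1 in log2 size, 76.1% of 67 changed by 0.5 and 52.2% of 67 changed by 0.25 were recovered, and 9 of 159 calls were unchanged probes. For swapped arrays with dye effects, the turned fit with a dye term recovered 92.4%, 59.7% and 26.9% at those sizes, and 5 of 124 calls were unchanged probes. The simulation assumed that the swapped arrays are known, and its dye effects were the measured mean ratios, taken as dye bias alone. On the measured ratios, the labelled fit keeps the turned contrast in its residual. Its median SE was 0.049, against 0.039 in the turned fit with a dye term. The simulated recovery and false calls for the labelled dyes therefore hold for less noise than that fit had.

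Alternatives were other background corrections, normalizations, filters, flag use, array weights, thresholds, each array left out, the processed table and the signs above.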

Results

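Messenger RNA levels were compared between the ileum, the last part of the small intestine, of wild-type (WT) mice and of NaS1-/- mice, which lack the sodium-sulfate cotransporter NaS1, the product of Slc13a1. NaS1 carries sulfate across the brush border of intestinal and kidney epithelium. Pooled WT and pooled NaS1-/- RNA were hybridised together on each of 4 arrays, 1 pool in Cy3 and the other in Cy5. Each array held 21766 mouse probes. The labels put WT in Cy3 and NaS1-/- in Cy5 on all 4 arrays, whereas the series text states that dyes were swapped for 2 sets and does not name them. The direction of every ratio below is therefore not settled, and ratios are given as Cy5 over Cy3. The labels do not say whether 1 pool or several were used per genotype, so p-values measure only the spread between the 4 hybridisations, which may be technical, and compare the pools.

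The files used here do not pair the probe identifiers with genes. The signal of Slc13a1, the gene lists set before the data were examined and named genes were therefore not analysed here, and probes are described by count and by 4 identifiers.

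Median probe intensity was 610, 637, 691 and 660 in Cy3 and 564, 571.5, 710 and 697 in Cy5 on arrays 1 to 4. Local background medians lay between 174 and 191 in Cy3 and between 113 and 118 in Cy5. Between 96.7% and 97.6% of probes were above background in Cy3 and between 96.6% and 97.2% in Cy5. The number of arrays limits the precision of every ratio. Across probes, which are not independent replicates, normalized ratios of arrays 1 and 4 correlated with a Pearson r of 0.876 and those of arrays 2 and 3 with 0.877. The other pairs of arrays had r between 0.714 and 0.762. In raw ratios, r was 0.906 for arrays 1 and 4, 0.928 for arrays 2 and 3 and between 0.850 and 0.891 for the others. By Spearman correlation of raw ratios, arrays 1 and 2 (0.915) exceeded arrays 1 and 4 (0.911).

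With the labelled dyes on all 4 arrays, 11991 of 21055 tested probes passed an adjusted p of 0.05 in limma. Of these, 6016 were higher and 5975 lower in the Cy5 channel, labelled NaS1-/-. The differences were small, with a median size of 0.29 on the log2 scale, or 1.23-fold, and 137 probes reached 1 in log2 size. Of those 137 probes, 8 were higher and 129 lower in Cy5. Any bias of a probe toward one dye is part of this ratio, because with the labelled dyes each pool was always in the same dye. Under the labels, these counts cannot separate a pool difference from a dye difference.

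Probes to be named had to pass the threshold, with 1 sign and a signal above background in both channels on all 4 arrays. The passing p and the shared sign were therefore set by the choice. Among such probes, CGEN_MOUSE_3000077_1 had the largest lower ratio of this fit. Its log2 Cy5/Cy3 ratio was -3.73 ± 0.77 (SD, n = 4), with a limma adjusted p of 0.00018 and a lower Cy5 signal on 4 of 4 arrays. CGEN_MOUSE_EXT_3102613_1 had the largest higher ratio, 1.24 ± 0.18 (SD, n = 4), with a limma adjusted p of 0.00011. Its Cy5 signal was higher on 4 of 4 arrays. It was dim, with raw intensities of 258 to 300 in Cy3 and 370 to 463 in Cy5, below the median probe. Its log2 ratio was 0.85 without background correction and 1.72 after background subtraction, so its size depended on background handling. Both calls hold for the labelled dyes only. With arrays 1 and 4 turned against 2 and 3 and a dye term, the ratios were -0.39 and -0.12 in that order, of arbitrary sign, with limma adjusted p of 0.468 and 0.315. Neither probe was called in any of the 6 fits with 2 arrays turned. Without a dye term this followed from the choice of probes with 1 sign on all 4 arrays, whose turned ratios offset each other. Both were chosen after their values were seen.

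Because the series text states a swap of 2 sets without naming them, each of the 3 ways of turning 2 arrays against the other 2 was fitted. These fits were added after the data were examined, and their sign is arbitrary. Without a dye term, limma called 0 probes in all 3 pairings. At an unadjusted limma p of 0.05, 569 probes (2.7%) passed with arrays 1 and 4 turned against 2 and 3. The number was 31 (0.15%) for arrays 1 and 2 against 3 and 4. For arrays 1 and 3 against 2 and 4 it was 30 (0.14%). Each share is below what chance alone would give at that p. On simulated swapped arrays, the fit without a dye term recovered 0% of changed probes at each size tested, including 1 in log2 size. The simulated dye effects were the measured mean ratios, taken as dye bias alone. The 0% holds under that assumption, which was not tested.

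With a dye term for each probe, limma called 520 of 20849 tested probes in the pairing of arrays 1 and 4 against 2 and 3, 229 in one direction and 291 in the other. The median size of these calls was 0.29 on the log2 scale, and 8 probes reached 1 in log2 size. In the other 2 pairings limma called 0 probes. At an unadjusted limma p of 0.05, 836 (4.0%) and 184 (0.88%) probes passed there, below the share expected by chance. In the pairing with calls, 3619 probes (17.4%) passed that unadjusted limma p. With 4 arrays and a dye term, each pairing's residual consists of the contrasts of the other 2 pairings. The contrast of arrays 1 and 4 against 2 and 3 had the largest spread (MAD), 0.068 against 0.049 and 0.040. It enters the error of the other 2 fits, so their 0 calls and low shares are not separate evidence for this pairing. On simulated swapped arrays, a wrongly turned fit with a dye term also recovered 0% at each size tested. The count of 520 was 192 without array 1, 13 without array 2, 7 without array 3 and 166 without array 4, each of which leaves a single array on one side of the pairing. It was 83 after background subtraction with a floor for low values and 986 without background correction. These p-values do not allow for the choice among 3 pairings. The files do not say that arrays 1 and 4 shared an orientation, so this pairing is a count and not a comparison of genotypes.

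Some probes had opposite ratios on the arrays. CGEN_MOUSE_3002506_1 had log2 Cy5/Cy3 ratios of -4.10, 4.68, 4.68 and -3.74 on arrays 1 to 4. Its raw Cy3 intensities were 14610, 740, 750 and 9788, and its raw Cy5 intensities 1438, 27206, 26849 and 1268. CGEN_MOUSE_3002665_1 had ratios of 1.68, -1.39, -1.26 and 1.58. In the fit as labelled these probes had mean log2 ratios of 0.38 with an SE of 1.71 and 0.15 with an SE of 0.59, with limma adjusted p of 0.862 and 0.839. With arrays 1 and 4 turned against 2 and 3, their limma adjusted p were 0.00014 and 0.0016 with a dye term, and 0.0652 and 0.121 without it. Both were chosen after their values were seen, as the largest of each sign called with a dye term in this pairing. They had to be above background in both channels on all 4 arrays. Opposite signs on the 2 pairs of arrays and a passing p were also conditions of the choice.

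**Figure D1:**
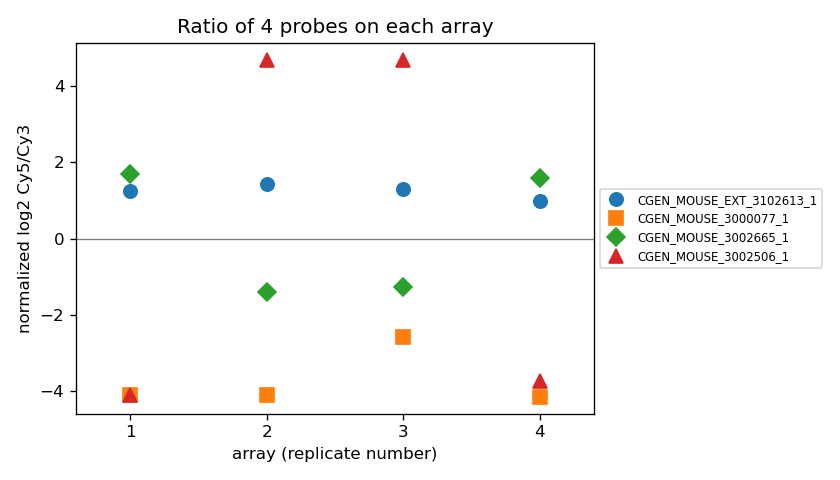
Normalized log2 Cy5/Cy3 ratio (vertical axis) of 4 probes on each of the 4 arrays (horizontal axis), with 1 point per probe and array and no averaging. CGEN_MOUSE_3000077_1 lies below 0 and CGEN_MOUSE_EXT_3102613_1 above 0 on all 4 arrays, while CGEN_MOUSE_3002506_1 runs from -4.10 on array 1 to 4.68 on array 2 and CGEN_MOUSE_3002665_1 from 1.68 to -1.39.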

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

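All tests of explanations in this part were chosen after the results were seen. CGEN_MOUSE_3000077_1 had a log2 Cy5/Cy3 ratio of -2.57 on array 3, far from the other arrays (-4.09, -4.09 and -4.15). It was 1 of 16 sets of 4 values examined for such a gap, and chance alone gives about 1 in 20. Of 2993 blank spots, which the comparisons of the report leave out, 23 were brighter than the median probe on all 4 arrays.

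Of 21055 tested probes, 11991 passed the threshold with the labelled dyes. If 2 arrays were swapped as the series text says, pool differences as the main source of these calls would give correlations below 0 between arrays of opposite orientation, whichever arrays they were. The lowest r between any pair of arrays was 0.714, and 98.2% of the calls had the same sign on all arrays. Both argue against that source under a swap, and probe-specific dye bias would give both. They are not separate tests, since the labelled fit calls mainly probes with 1 sign over the arrays. If the labelled dyes hold on all 4 arrays, pool differences and dye bias cannot be told apart, since both then predict correlations above 0 between all arrays.

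A ratio on all 4 arrays was available for 19680 probes. Of these, 908 were at least 0.5 in log2 size with the same sign on every array. An added comparison counted probes of that size on every array with opposite signs on 2 pairs of arrays. It found 18 for arrays 1 and 4 against 2 and 3, and 0 for the other 2 pairings. With a single array opposite to the rest, it found 2 for array 4 and 0 for each of the others. For 4 of the 18 probes the size was at least 1 on all 4 arrays. For these 4, picked by that size, it argues against a technical batch acting on the same pools in the labelled dyes. The other probes were not judged in this way. A swap of 2 arrays is a candidate explanation. Different pools on these arrays, in the labelled dyes, cannot be told apart from it, since a ratio such as 4.68 on array 2 for CGEN_MOUSE_3002506_1 against -4.10 on array 1 would arise either way, and the labels do not say how many pools there were. No orientation is assigned to any array from these values.

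Of the other 502 calls of that pairing, 360 had opposite signs on the same pairs at a smaller size, 77 had the same sign on all 4 arrays and 65 had another pattern or a missing value. The spread (MAD) of this contrast was 1.39 times the larger of the other pairings' in normalized ratios of probes. In raw, median-centred ratios it was 0.97 times in blank spots and 0.89 times in 231 of the control spots, so the measures are unlike. By SD, blank spots had their largest pairing spread here, 0.057 against 0.051 and 0.041. Those control spots did not, with 0.096 against 0.163 and 0.115. For the 502 calls a technical batch cannot be told apart from a swap: no label or header gives a batch, a small shift can turn a ratio near 0, and blank spots carry little labelled RNA. The 520 calls were spread unevenly over the 32 blocks, from 4 to 33 per block, with a permutation p of 1e-04, the smallest that 10000 permutations can give. After print-tip loess, which removes trends over blocks, 460 of the 520 were still called, which argues against such trends as the whole source.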

How the results depend on the processing

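All fits with arrays turned, and their alternatives, were chosen after seeing the data. The count of 11991 probes with the labelled dyes stayed within 1.5 times under the other background corrections, normalizations, filters and ignored flags. The same held for array weights and an adjusted p of 0.1. It was 8167 from the 3 distinct columns of the processed table, whose direction is unknown. Those 21744 rows were unfiltered and not matched to probes, so 8167 does not test the count of 11991. With the labelled dyes the count was 4462 with limma's B above 0 and 138 for averaged ratios of at least 1 with no test. Leaving out each array gave 9826 to 10706. With arrays 1 and 4 turned against 2 and 3 it was 520 with a dye term and 0 without. With arrays 1 and 2 against 3 and 4, or 1 and 3 against 2 and 4, limma gave 0 with and without a dye term. With 1 array turned, limma called 0 probes without a dye term and at most 1 with it.

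The count of 520 was 986 without background correction, 83 after subtraction with a floor, 1184 at an adjusted p of 0.1 and 8 for averaged ratios of at least 1. Leaving out each array gave 7 to 192. Each of these fits rested on fewer arrays than the count of 520. All had the same number of arrays, so that number cannot explain how their counts differed among themselves. The cause of the differences was not tested. With arrays 1 and 3 against 2 and 4, median centring gave 2 probes. In this pairing and in that of arrays 1 and 2 against 3 and 4, leaving out each array gave 0 to 1. The 4 named probes kept their sign and call in the 14 processing alternatives run for each. None was called in the 6 other sign and dye settings run for each, where the lowest limma adjusted p was 0.0652. Their choice for a call and a sign pattern in 1 setting partly fixed that outcome. Weighting negative flags was not run because there were 0 of them, and a scan or slide block was not run because no batch with more than 1 array was found. Those for Slc13a1, gene lists and named genes were not run, since probes were not paired with genes. Signal over background limits dim probes.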

Other observations

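The deposited table of processed values had 21744 filled and 53 empty rows and 4 columns with medians of -0.01, -0.0073, -0.011 and -0.0087. In 100% of the 21744 filled rows the column named for array 4, rounded to 2 decimals, equalled the column named for array 1 within 0.0051, so the table held 3 distinct columns. The normalized scanner ratios of these arrays differed, with an r of 0.876 across probes. Across the table's rows, r was 0.810 for columns 1 and 2, 0.658 for 1 and 3 and 0.617 for 2 and 3. For the normalized scanner ratios of the arrays so named it was 0.762, 0.745 and 0.877 in that order. The value exceeded by 0.1% of rows lay between 1.16 and 1.21 in the table's columns, and that undercut by 0.1% between -0.81 and -0.78. The scanner Cy5/Cy3 ratios had the longer tail on the lower side: 0.1% of probes lay below values between -1.48 and -1.36, and 0.1% above values between 0.96 and 1.13. In the table, 2 rows exceeded 3 in size, on an unknown log scale, in all 4 columns. One had 3.93, 4.25, 3.91 and 3.93, and the other 3.93, 3.86, -4.26 and 3.93. No direction was taken from these values.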
